A study of Mus musculus with 9 samples.

How the data were processed

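Liver RNA from 9 mice was measured on Affymetrix gene arrays, 1 per mouse, in 3 groups of 3: wild type, Clock mutant and mutants given a plasmid for wild-type Clock. Per the labels' protocols, the animals were kept in 12 h of light and 12 h of dark, began the 45% fat diet at 10 weeks of age, and the rescue animals were injected in week 10. RNA was extracted with TRIzol from tissue kept in RNAlater and was labelled with biotin, per the labels' protocols.

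The deposited values are log2 expression values per probe set. Per the submitters' processing notes they were made with RMA in Affymetrix Expression Console, whose versions are not given in the sources used here. RMA subtracts background, gives all arrays the same distribution of probe values and summarises probes into probe sets, so it can hide a shift common to most genes and compresses differences of dim genes. The log base was read from the values, which reach 13.86 at most and fit a 16-bit scanner only as log2. Nothing was missing, no identifier was repeated, and no per-sample column was left unused. Genes were not centred.

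The table held 35556 probe sets. The platform annotation used here gave a single gene symbol for 21789, several symbols for 1621 and none for 12146; probe sets with several symbols were not named. Entrez identifiers of 21698 probe sets matched the reference gene table (assembly GRCm38.p6, used for names, gene span and gene order and not for coordinates), 91 did not, and no symbol changed. Of the genes, 999 had more than 1 probe set, and the probe set with the highest mean over all arrays was kept, which left 19938 genes. Groups and replicate numbers came from the labels.

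All 9 arrays were fitted in 1 linear model with limma 3.58.1 in R 4.3.3 (statmod 1.5.0; figures with matplotlib 3.10.9 in Python 3.11.15), with 6 residual degrees of freedom and 8.475 prior degrees of freedom from eBayes. The 3 contrasts were mutant against wild type, rescue against mutant and rescue against wild type, with an F test across groups. Benjamini-Hochberg adjustment ran over the 19938 genes within each contrast, and genes with adjusted p under 0.05 were called. Differences are given on the log2 scale with the model's SE. "Adjusted over the list alone" means the same adjustment over the measured members of a list.

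There were 33 gene lists with 676 symbols, fixed before the data were examined; 601 symbols were measured and 75 were not analysed here. They were CLOCK-BMAL1 activated genes, genes repressed by REV-ERB, other clock components, xenobiotic metabolism, fatty acid synthesis, cholesterol synthesis, PPARA targets, lipid droplet and PPARG targets, glucose and glycogen, bile acids, amino acid and one-carbon metabolism, NAD and mitochondria, glucocorticoid targets, unfolded protein and integrated stress response, heat shock, NRF2 targets, acute phase, interferon response, inflammatory cytokines, cell cycle, male-biased, female-biased and sex chromosome genes, and markers of Kupffer cells, lymphocytes, neutrophils, stellate cells, endothelium, bile duct, red cells, exocrine pancreas, adipocytes and hepatocytes. Lists were tested with camera at the preset inter-gene correlation of 0.01, adjusted over the 33 lists, with an estimated correlation and with fry as alternatives.

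The samples, tests, alternatives and the rule for named genes were also fixed before the data were examined. The rule names, per comparison, Clock, the members of both clock lists, the 10 largest rises and 10 largest falls among called genes whose 3 against 3 values do not overlap (predicted genes left out), and up to 4 members of smallest p in each other list.

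Recovery was the projection of each array on the wild-type minus mutant difference over 24 clock genes, each wild-type and mutant array being set against means taken without it, with exact permutation tests in which the axis stayed fixed. Turned-back genes were those called in mutant against wild type and called in the opposite direction in rescue against mutant, set against 100 simulations of unchanged groups that shared the mutant arrays. A covariance of the 2 comparisons with different mutant arrays in each, and with 100 regroupings of scaled residuals, was added after the data were seen. Genes within 100 tested genes of Clock were compared with all others by Fisher's exact test.

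The model was tested on simulated data for 19938 genes with the real means and the spreads as moderated by eBayes. Error was drawn independently for each gene, so the simulated genes lacked the correlation of real ones. For mutant against wild type, 64% of genes changed by 0.5 on the log2 scale were called, and 98% of those changed by 1; 17 unchanged genes were called among 210. For rescue against mutant these were 56%, 100% and 9 among 198, and for rescue against wild type 50%, 98% and 7 among 195.

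Alternatives were the replicate number as a block, leaving out the dimmest 40% of genes, quantile normalization repeated, median centring, a trended and robust prior, array weights, the mean of all probe sets of a gene, all 28939 probe sets from the first annotated number on without collapse, other thresholds, the 6 arrays of a comparison alone, each array left out in turn, windows of 50 and 200 genes around Clock, and parts of the clock lists. Removal of a loess trend (span 0.3, degree 2) of each array's deviations on gene span and level was added after the data were seen, as was camera with an estimated correlation on those values.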

Results

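Gene expression was measured in the liver of 9 mice, with 1 Affymetrix array per animal. There were 3 wild-type C57BL/6J mice, 3 mice carrying the Clock-D19 mutation and 3 rescue mice. The mutation changes splicing of Clock and yields a CLOCK protein that still pairs with BMAL1 but activates transcription poorly. Rescue mice carried the same mutation and had received 35 µg of a plasmid for wild-type Clock by hydrodynamic tail-vein injection, which delivers DNA mainly to hepatocytes. All animals ate a diet with 45% fat for 5 weeks and were killed at zeitgeber hour 10, that is 10 h after lights on. The comparisons therefore address what the mutation changes in liver at this hour and which of those changes differ after Clock is supplied. A control injection of the wild-type and mutant animals is not described in the labels. The number of arrays limits the precision. The p-values of limma, fry and the permutation tests measure the spread between these animals. Camera at the preset correlation compares genes with genes, and Fisher's exact test counts genes, so their p-values do not measure that spread.

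After collapse to 1 probe set per gene, 19938 genes were tested. The first principal component held 38.4% of the variance. It placed the mutant arrays at -21.3, -26.1 and -18.7, the rescue arrays at 3.64, 2.36 and 1.53, and the wild-type arrays at 19.3, 14.2 and 25.1. An F test across the 3 groups called 2569 genes at an adjusted p under 0.05 (1561 without wild-type replicate 3 and 1611 without Clock mutant replicate 1).

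Clock itself was read first. Its log2 level was 9.97, 9.24 and 9.30 on the wild-type arrays, 10.88, 9.89 and 10.55 on the mutant arrays, and 10.33, 9.41 and 9.62 on the rescue arrays. It was 0.94 ± 0.26 (SE) higher in mutant than in wild-type liver (limma adjusted p = 0.0266, n = 3 per group), although the values of the groups overlapped; with a trended and robust prior the adjusted p was 0.139, and the call was also lost without wild-type replicate 2 (0.81, adjusted p = 0.0864) or 3 (0.83, 0.103) and without Clock mutant replicate 1 (0.72, 0.108) or 3 (0.88, 0.0715). The difference between rescue and mutant was -0.66 ± 0.26 (limma adjusted p = 0.168). It was called with array weights (-0.82, adjusted p = 0.0454) and with the replicate number as a block (-0.66, adjusted p = 0.0158). Clock was highest in replicate 1 and lowest in replicate 2 of each group. The difference between rescue and wild type was 0.28 ± 0.26 (adjusted p = 0.719). The probe set covers the whole gene, so it cannot separate the mutant transcript from the plasmid transcript and does not check the group labels.

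**Figure D1:**
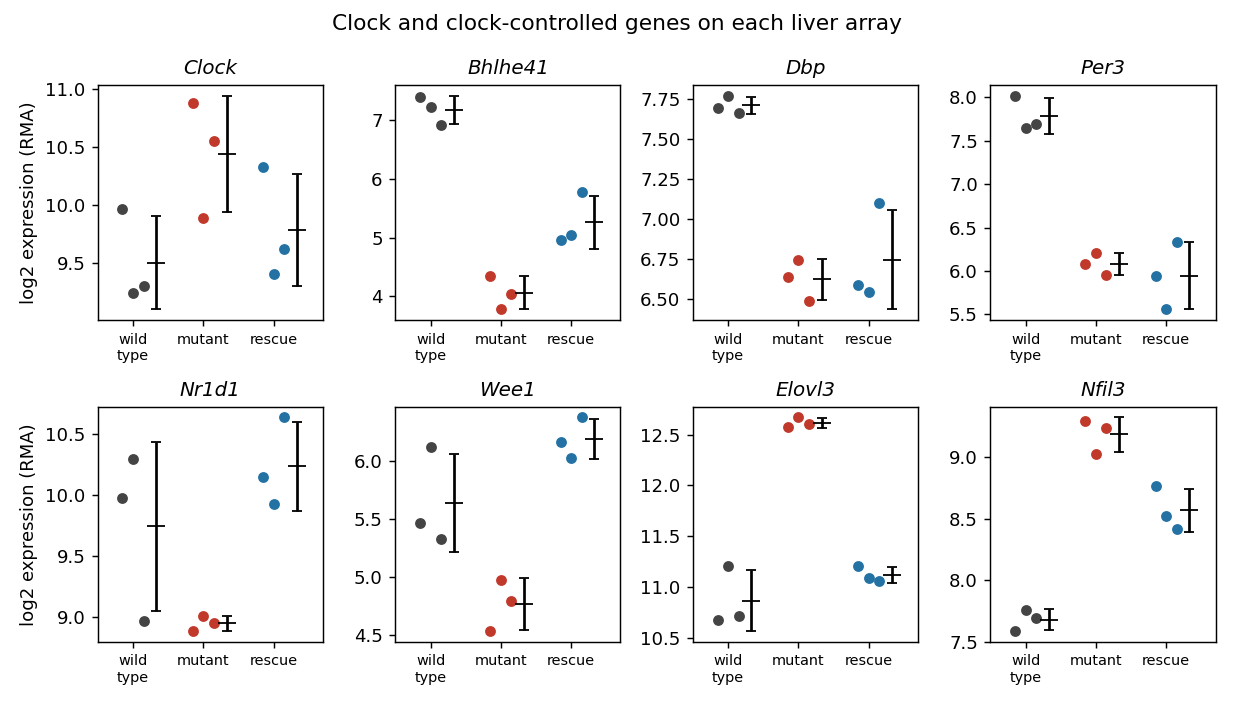
Log2 expression (vertical axes, RMA values, each with its own range) of 8 genes on the 9 arrays, by group; points are single mice, and the bar beside them is the mean with its SD (n = 3). Bhlhe41 averaged 7.18 in wild type, 4.07 in mutant and 5.26 in rescue, whereas Per3 averaged 7.79, 6.09 and 5.95.

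Clock mutant livers differed from wild-type livers most in the genes that CLOCK and BMAL1 activate. Of 19 measured members of that list, 16 fell, none rose and 3 did not pass; adjusted over the list alone, 17 fell. Bhlhe41, a repressor within the clock, fell by 3.12 ± 0.20 on the log2 scale, to a mutant level of 4.07 that lies below the median of the olfactory receptor genes (4.25 to 4.33 on the mutant arrays). The deubiquitinase gene Usp2 fell by 1.80 ± 0.15, the period gene Per3 by 1.70 ± 0.17, and Nampt, which encodes the rate-limiting enzyme of NAD salvage, by 1.51 ± 0.13 (adjusted p at most 2.8e-05 for each, limma, n = 3 per group). The list shifted down as a group, with a median of -0.87 (camera adjusted p = 8.34e-18, and adjusted p = 0.117 with an estimated correlation).

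The other members that fell ranged from Ciart at -1.34 ± 0.14 to Per1 at -0.46 ± 0.13. They included the D-box factors Dbp (-1.09 ± 0.14), Tef (-0.74 ± 0.12) and Hlf (-0.71 ± 0.10), the nuclear receptor genes Nr1d2 (-1.18 ± 0.16) and Nr1d1 (-0.80 ± 0.26), and Per2 (-0.67 ± 0.13). Nr1d1 rested on a wide spread, with wild-type values of 9.97, 10.30 and 8.96. It was not called with the replicate number as a block (limma adjusted p = 0.0626), with quantile normalization repeated (0.0734) or with a trended and robust prior (0.184). Nor was it called with the 6 arrays alone (0.0544) or without any 1 of 6 single arrays (0.0574 to 0.176). Per1 was likewise not called without wild-type replicate 1 or 2 or Clock mutant replicate 1 or 3 (-0.37 to -0.43, adjusted p = 0.0741 to 0.106). Cry2 (-0.18 ± 0.13), Gys2 (-0.34 ± 0.15) and Lonrf3 (0.08 ± 0.11) did not pass. Among 6 measured genes repressed by REV-ERB, 3 rose, none fell and 3 did not pass; adjusted over the list alone, 4 rose and 1 fell. Elovl3, a fatty acid elongase gene, rose by 1.76 ± 0.13 and the repressor gene Nfil3 was 2.84-fold higher (adjusted p under 0.05, limma). The other gene that rose was Clock, the mutated gene itself, and the list was not tested without it. Arntl, which encodes BMAL1, differed by -0.08 ± 0.12 (adjusted p = 0.679). That list shifted up (median 0.66, camera adjusted p = 0.0373, and adjusted p = 0.368 with an estimated correlation), but was not called without wild-type replicate 1 (0.70, adjusted p = 0.101), without Clock mutant replicate 1 (0.58, 0.0562) or 3 (0.64, 0.0587), or without the dimmest 40% of genes (0.0569). Of 9 other clock components, 1 rose, 1 fell and 7 did not pass (camera adjusted p = 0.694).

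Across the transcriptome, 3068 genes changed, of which 1270 rose and 1798 fell; 147 of them changed at least 2-fold. Without wild-type replicate 3 the count was 1695 (533 rose, 1162 fell), without Clock mutant replicate 1 it was 2035 (693 and 1342), and without Clock mutant replicate 3 the rises were 782. With each array centred on its median, 736 rose and 2078 fell. The largest measured rises were in the neurotrophin receptor gene Ntrk2 (2.75 ± 0.16), Elovl3 and Nfil3. The water channel gene Aqp8 rose 2.82-fold, the choline kinase gene Chka by 1.43 ± 0.15, and Coq8a, a coenzyme Q synthesis gene, by 1.36 ± 0.12. After Bhlhe41 the largest measured falls were in Nat8f5 (-2.31 ± 0.26), the interferon-inducible Ifi205 (-2.27 ± 0.21), the desmoglein gene Dsg1c (-2.16 ± 0.15), the macrophage receptor gene Vsig4 (-2.14 ± 0.14), Ankrd12 (-2.07 ± 0.14), the growth factor gene Nrg4 (-2.06 ± 0.13), the carboxylesterase gene Ces1g (-2.02 ± 0.20) and the neprilysin gene Mme (-1.84 ± 0.13). The dimmer group of Ntrk2 (wild type, 2.84) and of Ifi205 (mutant, 2.27) lay below the median of the olfactory receptor genes on those arrays, as did Bhlhe41 in mutant. That level need not be above background, so the sizes and ranks of the 3 changes are uncertain and the changes may be larger than measured.

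Markers of endothelial and Kupffer cells were lower in the mutant livers. Of 21 endothelial markers 12 fell, none rose and 9 did not pass, and adjusted over the list alone 16 fell and 1 rose. Bmp2 fell by 1.18 ± 0.15, Mrc1 by 0.96 ± 0.13, Kdr by 0.86 ± 0.11 and Fcgr2b by 0.84 ± 0.10. The median of the list was -0.47 (camera adjusted p = 8.11e-11, and adjusted p = 0.347 with an estimated correlation). Of 19 Kupffer cell and macrophage markers 9 fell and 10 did not pass, and adjusted over the list alone 10 fell and 1 rose. Besides Vsig4, Adgre1 fell by 1.40 ± 0.21, Cd68 by 1.19 ± 0.16 and Timd4 by 0.98 ± 0.14. The median of that list was -0.43 (camera adjusted p = 1.02e-06, and adjusted p = 0.347 with an estimated correlation).

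Other cell type lists were not called in the mutant livers. Only 4 of 17 lymphocyte, 5 of 10 bile duct and 0 of 13 neutrophil markers lay outside the dimmest 40% of genes. Of 22 stellate cell and fibroblast markers 18 did so. RMA compresses differences of dim genes, so a fall of lymphocyte, bile duct or neutrophil markers could have been missed. Among 22 stellate cell and fibroblast markers 5 fell and 1 rose (camera adjusted p = 0.127), with Rgs5 at -0.86 ± 0.12 and Lrat at -0.81 ± 0.15. Among 17 lymphocyte markers only Cd3g passed, at -0.66 ± 0.15 (adjusted p for the list = 0.35). No member passed among 13 neutrophil markers (0.857). Of 10 bile duct markers 1 rose and 2 fell (0.96), of 5 red cell markers 1 fell (0.96), of 13 exocrine pancreas markers 1 rose (0.232), of 8 adipocyte markers 1 fell (0.88) and of 17 hepatocyte markers 1 rose (0.313); the values in parentheses are camera adjusted p.

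Metabolic genes changed in the same arrays in which the endothelial and Kupffer markers were lower. In xenobiotic metabolism, 8 of 29 measured genes fell and 1 rose, and adjusted over the list alone 9 fell and 1 rose. With Ces1g, the carboxylesterase gene Ces1d fell by 0.84 ± 0.10 and the cytochrome gene Cyp3a13 by 0.69 ± 0.10 (list median -0.19, camera adjusted p = 4.78e-04, and adjusted p = 0.347 with an estimated correlation). In amino acid catabolism and one-carbon metabolism, 10 of 29 genes rose and none fell, and adjusted over the list alone 13 rose. Cbs, which encodes the cystathionine synthase, rose by 1.10 ± 0.18, the glycine methyltransferase gene Gnmt by 1.01 ± 0.13 and Fah, of tyrosine breakdown, by 0.70 ± 0.14 (list median 0.30, camera adjusted p = 8.97e-04, and adjusted p = 0.659 with an estimated correlation).

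The other metabolic lists did not shift as groups, although members changed. Of 21 cholesterol synthesis genes 4 rose, among them Hmgcs1 (0.98 ± 0.10), Fdps (0.86 ± 0.14) and Mvd (0.80 ± 0.11), with a camera adjusted p of 0.465. Of 24 genes of fatty acid and triglyceride synthesis 4 rose and 2 fell (0.313), and the phosphatidate phosphatase gene Lpin1 fell by 1.09 ± 0.13. Of 30 PPARA targets 4 rose and 7 fell (0.313), and the acyl-CoA thioesterase genes Acot3 and Acot1 fell by 1.40 ± 0.21 and 0.84 ± 0.12. Of 21 lipid droplet and PPARG target genes 6 rose and 1 fell (0.074), with Lgals1 at 1.23 ± 0.17 and Plin2, which coats lipid droplets, at 0.74 ± 0.12. Of 23 NAD and mitochondrial genes 4 rose and 6 fell (0.349): the nicotinamide riboside kinase gene Nmrk1 fell by 1.33 ± 0.14 and Haao, of NAD synthesis from tryptophan, rose by 0.89 ± 0.13. Of 26 bile acid genes 5 rose and 2 fell (0.856), with Hsd3b7 at 0.94 ± 0.15, and of 25 glucose and glycogen genes 3 rose and 3 fell (0.429).

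Stress, immune and sex-related lists were not called either, with the values as deposited. Camera adjusted p was 0.127 for 18 glucocorticoid targets (1 rose, 4 fell), 0.35 for 27 genes of the unfolded protein and integrated stress response (5 rose, 2 fell, with Atf5 at 0.90 ± 0.13), 0.698 for 18 heat shock genes (2 rose, 2 fell) and 0.353 for 19 NRF2 targets (1 fell). It was 0.35 for 28 acute phase genes (3 rose, 4 fell), 0.313 for 28 interferon-stimulated genes (1 rose, 6 fell) and 0.074 for 20 inflammatory cytokine and chemokine genes. Of those 20, 4 fell, including the adhesion molecule gene Vcam1 (-1.24 ± 0.12) and the chemokine gene Cxcl9 (-1.22 ± 0.14). Of 29 cell cycle genes 2 rose and 5 fell (0.313), with Mki67 at -0.76 ± 0.14 and Top2a at -0.63 ± 0.11. Of 17 male-biased genes 3 rose and 5 fell (0.35), with the repressor gene Bcl6 at 1.16 ± 0.17, and of 19 female-biased genes 1 rose and 4 fell (0.398). Of 4 sex chromosome genes 2 fell (0.2).

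The change in a gene also followed the length of its genomic span. Spearman's rho between span and the mutant against wild-type difference, across 19856 genes, which are not independent replicates, was -0.236. With genes ordered by span in 5 equal groups, 330 rose and 67 fell in the group of shortest genes, and in that of the longest 146 rose and 674 fell. The rho of each array's deviation from the mean of all arrays was -0.162, -0.215 and -0.170 in the mutants, against 0.182, 0.106 and 0.173 in wild type and 0.113, -0.028 and 0.101 in rescue. With this trend removed, an alternative chosen after the data were seen, 2586 genes changed, 2043 of them among the 3068. The fatty acid synthesis list (camera adjusted p = 0.00678), the lipid droplet list (0.0397), the inflammatory list (0.00396) and the cell cycle list (0.0397) were then called as well, the first pair up and the others down. With an estimated correlation and the trend removed their adjusted p was 0.597, 0.437, 0.356 and 0.427.

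**Figure D2:**
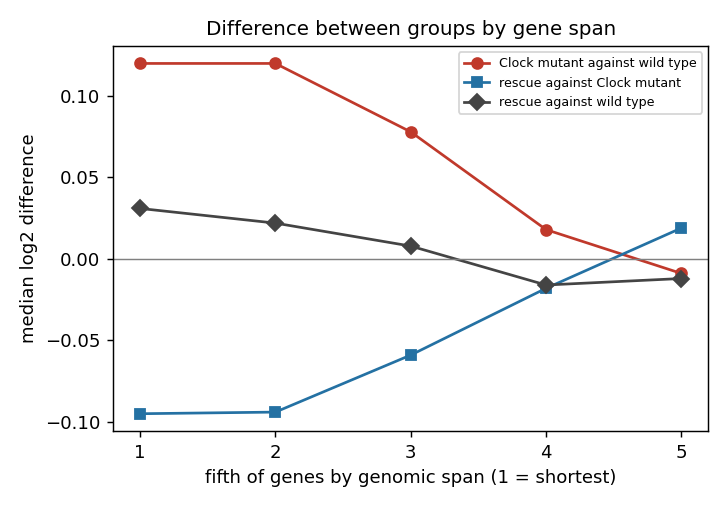
Median log2 difference (vertical axis) in 5 equal groups of genes ordered by genomic span (horizontal axis, 1 is the shortest), for the 3 comparisons. The mutant against wild-type median was 0.12 in the shortest group and -0.0089 in the longest, and the rescue against mutant median was -0.095 and 0.019.

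Wild-type and mutant animals could also differ around Clock if the mutation had been bred onto another background, which brings flanking sequence. Whether it was so bred is not known here, and genes near Clock were counted. Among the 100 tested genes on each side, 41 of 200 (20.5%) changed between mutant and wild type, against 3027 of 19738 others (15.3%; odds ratio 1.42, confidence interval 0.982 to 2.02, Fisher's exact test, two-sided p = 0.0487). The odds ratio was 1.13 (p = 0.526, Fisher's exact test) with the span trend removed and 1.19 (p = 0.322) with quantile normalization repeated. It turned below 1 without wild-type replicate 1 (0.954) and without Clock mutant replicate 1 (0.923). It was larger with median centring (1.83, p = 6.81e-04), without the dimmest 40% of genes (1.54, p = 0.00419) and with 50 genes on each side (2.04, p = 0.00307), all by Fisher's exact test, so it depended on the setting. For rescue against wild type it was 1.8 (p = 0.143) and for rescue against mutant 0.916 (p = 1), both by Fisher's exact test. The endothelial marker Kdr (-0.86) is among the 10 nearest tested genes on either side, so its change need not reflect endothelial cells. Of the other nearest genes, Ppat, an enzyme gene of purine synthesis singled out after its values were seen, was -1.12 in mutant (adjusted p = 2.65e-04) and -1.03 in rescue (adjusted p = 0.00173) relative to wild type.

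Rescue livers differed from mutant livers in a few clock genes, while for most no difference passed. Of 19 CLOCK-BMAL1 activated genes, 4 rose, none fell and 15 did not pass; adjusted over the list alone, 5 rose. Alas1, the first enzyme gene of heme synthesis, rose by 1.62 ± 0.15, the cell cycle kinase gene Wee1 by 1.42 ± 0.18, Nr1d1 by 1.29 ± 0.26 and Bhlhe41, from its dim mutant level, by a measured 1.20 ± 0.20 (adjusted p = 1.37e-04, 0.00113, 0.0167 and 0.00824, limma, n = 3 per group). Per3 (-0.14 ± 0.17), Usp2 (0.01 ± 0.15), Nampt (0.08 ± 0.13) and Dbp (0.12 ± 0.14) did not pass. The list shifted up (median 0.11, camera adjusted p = 0.0011, and adjusted p = 0.378 with an estimated correlation); it was not called without the dimmest 40% of genes (adjusted p = 0.151) or with fry (0.112).

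Of 6 genes repressed by REV-ERB, 2 fell, none rose and 4 did not pass; adjusted over the list alone, 5 fell and 1 rose. Elovl3 fell 2.84-fold and Nfil3 by 0.62 ± 0.12, and Arntl was at -0.44 ± 0.12 (adjusted p = 0.0583), with a call in 7 alternatives, among them quantile normalization repeated (0.0336) and the span trend removed (-0.57, 0.0204). That list shifted down (median -0.53, camera adjusted p = 0.00287, and adjusted p = 0.371 with an estimated correlation). Clock, which the plasmid carries, is among its 6 measured members, and the list was not tested without Clock. The 9 other clock components had no call (camera adjusted p = 0.223).

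In all, 759 genes changed between rescue and mutant, 520 up and 239 down, and 42 of them at least 2-fold. The count was 1178 without the dimmest 40% of genes, 1210 with a trended and robust prior and 1334 with array weights. With the trend on gene span and level removed it was 654, of which 491 were among the 759. With quantile normalization repeated, 541 rose and 438 fell, and without rescue replicate 1, 289 rose and 257 fell. Ifi205 rose by a measured 2.30 ± 0.21, an uncertain size since its mutant level need not be above background, Nat8f5 by 1.93 ± 0.26, Gpr65, a proton-sensing receptor gene, by 1.79 ± 0.16, and Pfkfb3, an activator gene of glycolysis, by 1.56 ± 0.17. Cib3 (1.48 ± 0.21), the acetylcholine receptor gene Chrna4 (1.42 ± 0.23), Ces1g (1.34 ± 0.20) and Cyp2b9 (1.32 ± 0.21) rose as well. Cyp7a1, the rate-limiting enzyme gene of bile acid synthesis, fell by 1.71 ± 0.28, the proton pump gene Atp6v0d2 by 1.64 ± 0.27, Lgals1 by 1.33 ± 0.17, Serpina12 by 1.14 ± 0.13, the nicotinamide methyltransferase gene Nnmt by 1.09 ± 0.16, the lipogenic regulator gene Thrsp by 0.98 ± 0.24 and Moxd1 by 0.93 ± 0.16. The ornithine aminotransferase gene Oat and the proline dehydrogenase gene Prodh fell as well (limma adjusted p = 0.00839 and 0.00217). With a trended and robust prior Cyp7a1 (adjusted p = 0.0662), Atp6v0d2 (0.0542) and Thrsp (0.157) were not called, nor was Thrsp with the span trend removed (0.051).

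Metabolic lists that shifted between rescue and mutant were those of xenobiotic, lipid droplet and amino acid genes. In xenobiotic metabolism 7 of 29 genes rose and none fell, and adjusted over the list alone 8 rose and 2 fell; besides Alas1, Ces1g and Cyp2b9, the drug efflux pump gene Abcb1a rose by 1.30 ± 0.15 (median 0.12, camera adjusted p = 0.00106). Of 21 lipid droplet and PPARG target genes 3 fell and 1 rose, and adjusted over the list alone 7 fell and 1 rose; Fitm1 fell by 0.64 ± 0.12 and Plin4 by 0.53 ± 0.09 (median -0.30, camera adjusted p = 0.0013). With an estimated correlation, adjusted p was 0.371 for both lists. Of 29 amino acid and one-carbon genes 4 fell and none rose, and adjusted over the list alone 8 fell; Gnmt fell by 0.78 ± 0.13, the alanine aminotransferase gene Gpt by 0.78 ± 0.14 and the urea cycle gene Asl by 0.58 ± 0.13 (median -0.24, camera adjusted p = 0.00921, and adjusted p = 0.684 with an estimated correlation). Without rescue replicate 2 the median of this list was -0.06 and the list was not called (adjusted p = 0.265), nor was Asl (-0.45, adjusted p = 0.0891).

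Endothelial, Kupffer and stellate cell markers were higher in rescue than in mutant livers in the same comparison. Of 21 endothelial markers 3 rose and none fell, and adjusted over the list alone 12 rose: Mrc1 rose by 0.50 ± 0.13, Ptprb by 0.49 ± 0.10 and Kdr by 0.45 ± 0.11 (median 0.29, camera adjusted p = 4.59e-07, and adjusted p = 0.371 with an estimated correlation). Of 19 Kupffer markers Vsig4 rose by 1.10 ± 0.14 and Mpeg1 fell by 0.63 ± 0.13, and adjusted over the list alone 2 rose and 1 fell (median 0.17, camera adjusted p = 0.013, and adjusted p = 0.54 with an estimated correlation). Of 22 stellate markers 4 rose, both over all genes and adjusted over the list alone, with Rgs5 at 0.57 ± 0.12 and the vimentin gene Vim at 0.49 ± 0.10 (median 0.10, camera adjusted p = 0.013, and adjusted p = 0.371 with an estimated correlation). The stellate list was not called without Clock mutant replicate 1 (median 0.01, adjusted p = 0.075), nor the Kupffer list without rescue replicate 1 (median 0.14, adjusted p = 0.0902). With the span trend removed the endothelial list was still called (median 0.23, adjusted p = 3.54e-05, and adjusted p = 0.412 with an estimated correlation) but no single member passed: adjusted p was 0.058 for Kdr, which lies near Clock, 0.104 for Ptprb and 0.144 for Mrc1. The Kupffer list was not called without the dimmest 40% of genes either (0.288). Spearman's rho between gene span and this difference was 0.216.

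Male-biased and sex chromosome genes shifted as well, whereas the 19 female-biased genes did not (2 rose, 1 fell, camera adjusted p = 0.393). The sex chromosome list pools Y-linked genes with Xist, so its direction cannot be read as male or female. Of 17 male-biased genes 3 rose and 1 fell, and adjusted over the list alone 6 rose and 2 fell; the complement gene C6 rose by 0.76 ± 0.12, Susd4 by 0.64 ± 0.11 and Cyp4a12a by 0.56 ± 0.11 while Elovl3 fell (median 0.10, camera adjusted p = 0.0274). The male-biased call was lost without rescue replicate 3 (median 0.03, adjusted p = 0.101), without Clock mutant replicate 1 (0.06, 0.075), without the dimmest 40% of genes (0.151) and with the span trend removed (0.176). None of the 4 sex chromosome genes passed over all genes and 1 rose adjusted over the list alone, with Xist at 0.49 ± 0.14 (adjusted p = 0.0585, and called in alternatives such as quantile normalization repeated, 0.0402, and the span trend removed, 0.0309; list median 0.29, camera adjusted p = 0.00926). The sex chromosome call was lost without the dimmest 40% of genes (0.151) and with the span trend removed (median 0.17, adjusted p = 0.0583). With an estimated correlation, adjusted p was 0.371 for the male-biased and the sex chromosome list. Single calls outside these lists included the fall of Pdk4, a brake on glucose oxidation (-0.75 ± 0.12), the rise of Acot1 (0.67 ± 0.12), the fall of the pyruvate carboxylase gene Pcx (-0.51 ± 0.11) and the rise of the glutathione synthesis gene Gclc (0.52 ± 0.11). The remaining 23 lists had camera adjusted p of at least 0.1, none of them called.

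Of 43 called genes followed through the settings, 15 lost the call without some single array. These were Nr1d1, Nfil3, Mrc1, Ptprb, Kdr, Mpeg1, Rgs5, Vim, Thrsp, Asl, Fitm1, Acot1, Cyp4a12a, Gclc and Pcx. The rescue against mutant calls rested on few animals: without rescue replicate 3 the count was 201, without rescue replicate 2 it was 202, and without Clock mutant replicates 1, 2 or 3 it was 200, 323 or 340. Other splits of the same 6 arrays gave up to 17 shifted lists, against 10 here, so the number of lists does not stand apart.

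Taking the clock genes together, expression in each mouse was projected on the line from the mutant mean, at 0%, to the wild-type mean, at 100%, over 24 clock genes without Clock itself. Each mutant and wild-type mouse was set against means taken without it, so that these groups need not average 0% and 100%. The rescue livers lay at 37.2% on average (n = 3), with single values of 31.3, 27.2 and 53.0%. Wild-type livers lay at 97.8% ± 10.5 (SD) and mutant livers at 1.08% ± 4.04. No rescue value overlapped the wild-type values (87.5 to 109%) or the mutant values (-2.37 to 5.53%). The exact permutation p was 0.1 against either group, the smallest that 3 against 3 animals can give, and the line was not redrawn for each permutation, so it is no evidence of a difference. With the genes repressed by REV-ERB alone the rescue mean was 68.8% and with the activated genes alone it was 30.4%. The projection weights each gene by the square of its difference between wild type and mutant. Bhlhe41, with its dim mutant level, therefore weighs most, and overshoot such as that of Alas1 (177%) counts as recovery. Among the genes of largest difference, Bhlhe41 recovered 38.4%, Usp2 0.367%, Elovl3 85.7% and Per3 -8.08%, so 37.2% does not describe a typical gene.

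Of the 18 clock genes called in the mutant comparison, 6 were called in the opposite direction between rescue and mutant: Alas1, Wee1, Nr1d1, Bhlhe41, Elovl3 and Nfil3. Nr1d1 counts only while its mutant call holds, and it was lost in both comparisons with a trended and robust prior (adjusted p = 0.184 and 0.0937). Relative to wild type, 12 were still called in the mutant direction, Alas1 was called in the opposite direction, and 2 of the 18, Bhlhe40 (-0.87, adjusted p = 0.0567) and Tspan4 (-0.44, adjusted p = 0.0648), were called in neither rescue comparison. Both were called below wild type without the dimmest 40% of genes (adjusted p = 0.0357 and 0.0334), with quantile normalization repeated (0.0486 and 0.0392), with median centring (0.0474 and 0.0375) and with the span trend removed (0.0326 and 0.0473). Bhlhe40 was also called without rescue replicate 1 (0.0479) or 3 (0.0327), and Tspan4 with a trended and robust prior (0.0377). Single genes recovered between -23.6% (Tef) and 177% (Alas1) of the mutant difference.

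**Figure D3:**
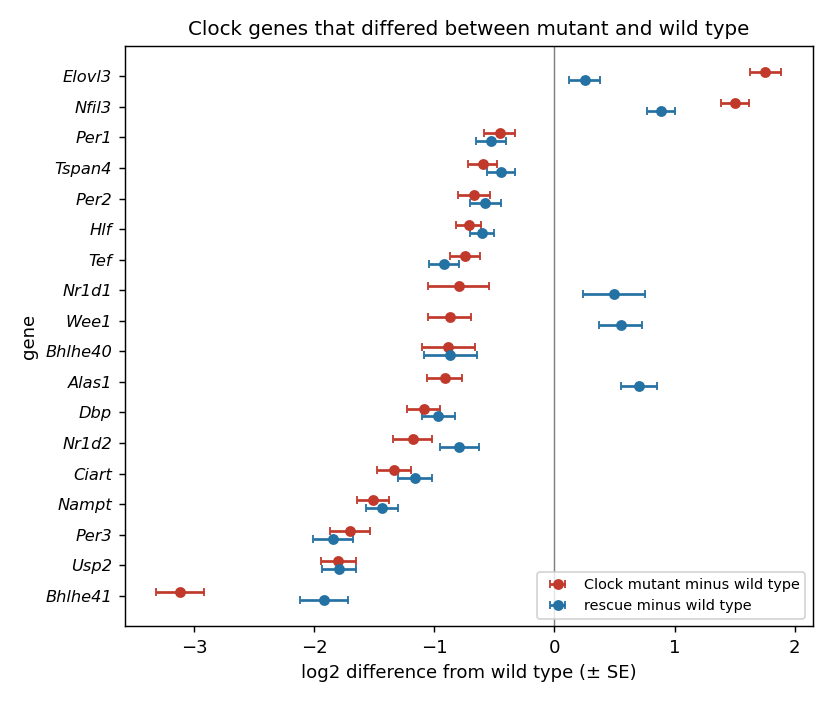
Log2 difference from wild type (horizontal axis, with its SE) of the 18 clock genes called between mutant and wild type, in mutant (red) and rescue (blue), 3 mice per group. Bhlhe41 lay at -3.12 in mutant and -1.92 in rescue, whereas Usp2 lay at -1.80 and -1.79.

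Over all genes, 564 of the 3068 mutant changes were turned back in rescue. Of these, 408 had fallen and rose again, against 46.9 for independent lists of the same lengths, and 156 had risen and fell again, against 15.2. Both comparisons use the mutant arrays. Chance with no effect in any group, over 100 simulations, turned back at most 1 gene, but such groups call almost none, so this is no measure of what shared mutant arrays add to real changes. The covariance of the log2 differences was -0.0476, against a simulated -0.00812, and their correlation across genes was -0.716, against -0.499. With 1 mutant array in 1 comparison and the other mutant arrays in the other, so that none was shared, the covariance was -0.0386 to -0.0368 over the 6 ways to do so, against -0.0181 to 0.0283 for regrouped residuals. Part of the count of 564 may come from the shared arrays, because 3 mutants cannot be split into separate sets of at least 2 for a count. Of the 564, 34 were still called between rescue and wild type, and 2176 of the 3068 were called in neither rescue comparison. The number turned back was 151 or 155 without rescue replicate 3 or 2 and 154, 248 or 260 without Clock mutant replicate 1, 2 or 3. It was 924 without the dimmest 40% of genes, 904 with a trended and robust prior and 938 with array weights. With the trend on gene span and level removed it was 469. The span trend ran in opposite directions in the 2 comparisons (Spearman's rho -0.236 and 0.216). It may therefore add to the 564 and to the covariance over all genes, which was not computed with the trend removed.

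Rescue livers still differed from wild-type livers in most CLOCK-BMAL1 activated genes. Of 19, 11 were lower, Alas1 was higher and 7 did not pass; adjusted over the list alone, 13 were lower and 2 higher. Bhlhe41 was lower by -1.92 ± 0.20, Per3 by -1.84 ± 0.17, Usp2 by -1.79 ± 0.15, Nampt by -1.44 ± 0.13, Ciart by -1.16 ± 0.14 and Dbp by -0.97 ± 0.14, whereas Alas1 was 0.71 ± 0.15 higher (median of the list -0.60, camera adjusted p = 2.68e-14, and adjusted p = 0.112 with an estimated correlation). Among 6 genes repressed by REV-ERB, Nfil3 was 0.89 ± 0.12 higher and Arntl was lower at -0.52 ± 0.12, both also when adjusted over the list alone (camera adjusted p = 0.408), and Elovl3 was at 0.25 ± 0.13 (adjusted p = 0.426). No other clock component was called.

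In all, 454 genes differed between rescue and wild type, 185 higher and 269 lower, and 56 of them at least 2-fold. The count was 711 without the dimmest 40% of genes and 704 with a trended and robust prior. With each array centred on its median, 154 were higher and 374 lower. Ntrk2 was a measured 2.34 ± 0.16 higher than its dim wild-type level, Chrna4 1.82 ± 0.23, Chka 1.75 ± 0.15, Pfkfb3 1.68 ± 0.17, Gpr65 1.59 ± 0.16, Cib3 1.41 ± 0.21, Asap2 1.31 ± 0.10, the mitochondrial chaperone gene Clpx 1.23 ± 0.12 and Ptprc, which encodes CD45, 1.21 ± 0.14. Cyp7a1 was at -2.17 ± 0.28, the uridine phosphorylase gene Upp2 at -1.70 ± 0.15, Gpcpd1 at -1.70 ± 0.17, Coq10b at -1.68 ± 0.11 and Nrg4 at -1.62 ± 0.13. Cyp7a1 varied between the rescue animals, with an SD of 0.84 against 0.236 in wild type. Of the 454 genes, 92 were not called between mutant and wild type.

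Kupffer and endothelial markers remained below wild type as lists. Of 19 Kupffer markers 6 were lower, with Vsig4 at -1.04 ± 0.14, Cd68 at -0.99 ± 0.16 and Timd4 at -0.75 ± 0.14, and adjusted over the list alone 7 were lower (median -0.31, camera adjusted p = 5.5e-06, and adjusted p = 0.296 with an estimated correlation). Of 21 endothelial markers 2 were lower, Bmp2 at -0.75 ± 0.15 and Fcgr2b at -0.57 ± 0.10, and adjusted over the list alone 8 were lower (median -0.18, camera adjusted p = 4.65e-05, and adjusted p = 0.566 with an estimated correlation). Spearman's rho between gene span and this difference was -0.114.

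In the same arrays 6 further lists shifted. Cholesterol synthesis genes were higher (median 0.16, camera adjusted p = 7.94e-04, and adjusted p = 0.508 with an estimated correlation); 1 of 21 passed, Hmgcs1 at 0.81 ± 0.10, and adjusted over the list alone 2 passed. That list was not called without rescue replicate 1 (median 0.11, adjusted p = 0.0843). Genes of the unfolded protein and integrated stress response were higher (median 0.07, camera adjusted p = 0.00188, and adjusted p = 0.508 with an estimated correlation); of 27, 3 were higher and Herpud1 was lower (-0.86 ± 0.13), and adjusted over the list alone 9 were higher and 1 lower. Among these were Atf5 at 0.71 ± 0.13 and the chaperone gene Calr at 0.63 ± 0.11. Glucocorticoid targets were lower (median -0.25, camera adjusted p = 7.97e-04, and adjusted p = 0.345 with an estimated correlation); 1 of 18 passed, Per1, and 7 adjusted over the list alone.

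Acute phase genes were lower (median -0.13, camera adjusted p = 0.00188, and adjusted p = 0.597 with an estimated correlation); 4 of 28 passed, among them Il6ra (-0.78 ± 0.14) and Saa4 (-0.60 ± 0.13), and 8 adjusted over the list alone. The acute phase list was not called without wild-type replicate 1 (median -0.10, adjusted p = 0.132) or without the dimmest 40% of genes (0.29). Interferon-stimulated genes were lower (median -0.11, camera adjusted p = 7.97e-04, and adjusted p = 0.396 with an estimated correlation); 1 of 28 passed, Ifih1 at -0.50 ± 0.12, and 6 adjusted over the list alone. Ifih1 was not called with quantile normalization repeated (adjusted p = 0.0538), with the 6 arrays alone (0.0664), with the span trend removed (0.0786) or without any 1 of 7 single arrays (-0.38 to -0.52, adjusted p = 0.0541 to 0.162). Cell cycle genes were lower (median -0.17, camera adjusted p = 0.00165, and adjusted p = 0.112 with an estimated correlation); 1 of 29 passed, Top2a at -0.55 ± 0.11, and adjusted over the list alone 5 were lower and 1 higher. With the mean of all its probe sets Top2a was at -0.24 (adjusted p = 0.408), and the list was not called without the dimmest 40% of genes (adjusted p = 0.348). Outside the shifted lists, Nmrk1 (-1.34 ± 0.14), Lpin1 (-1.26 ± 0.13), Cxcl9 (-1.08 ± 0.14), Vcam1 (-0.86 ± 0.12) and Cd36 (-0.81 ± 0.16) were lower, and Abcb1a (0.99 ± 0.15), Plin2 (0.78 ± 0.12) and Xist (0.77 ± 0.14) were higher. The other 24 lists were not called.

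Of 49 called genes followed through the settings, 10 lost the call without some single array. These were Alas1, Nr1d2, Per1, Per2, Arntl, Bmp2, Cd36, Saa4, Ifih1 and Top2a. The count of 454 was 242 without wild-type replicate 1, 233 without wild-type replicate 3, and 282, 254 or 264 without rescue replicate 1, 2 or 3. Other splits of these 6 arrays gave up to 12 shifted lists, against 9 here. Without rescue replicate 2 the balance turned to 138 higher and 116 lower, and without wild-type replicate 1 it was 122 and 120.

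**Figure D4:**
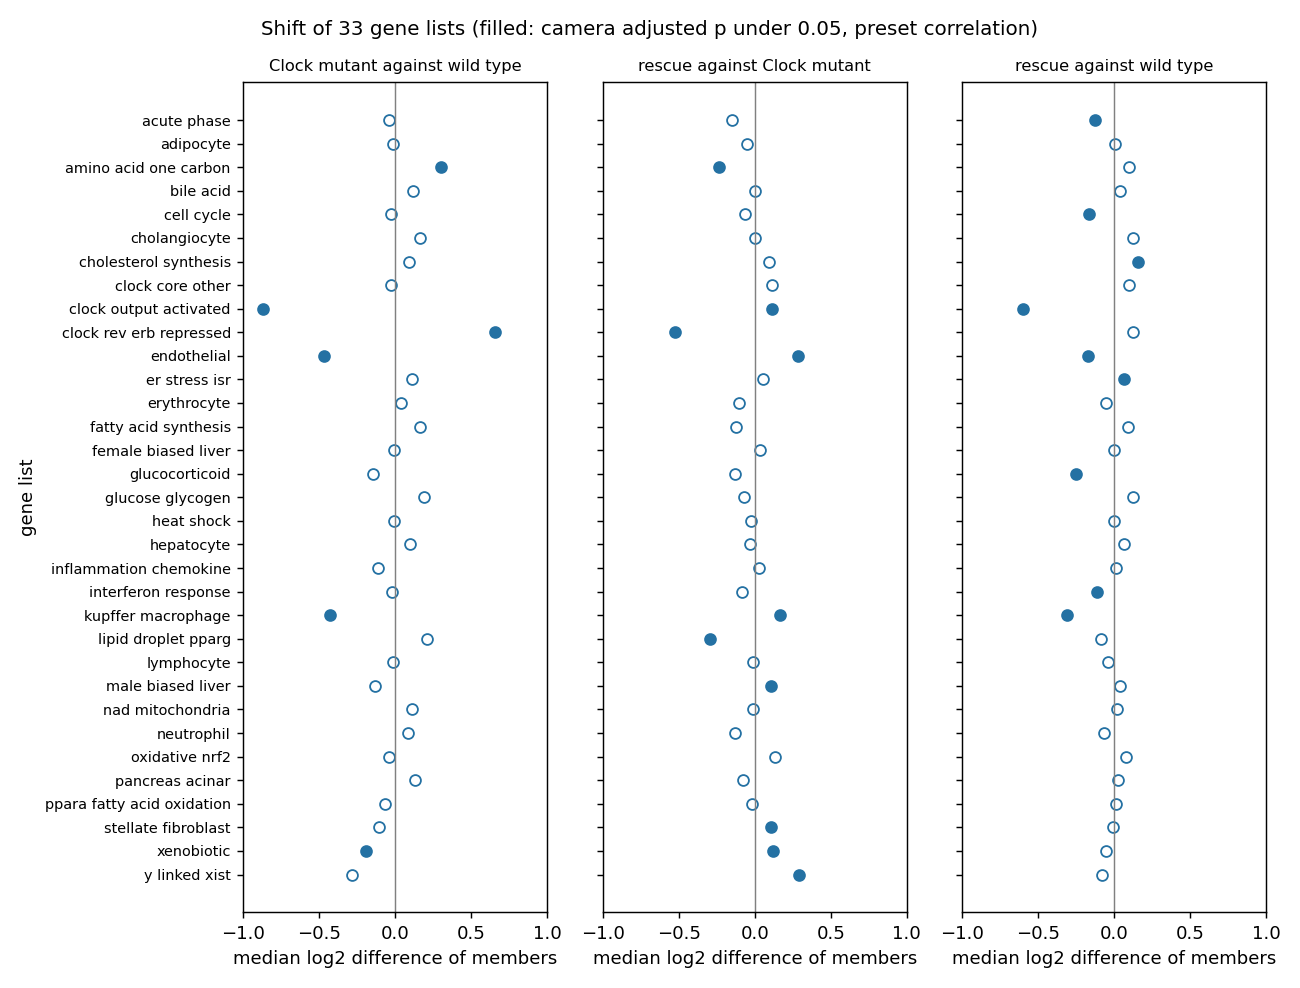
Median log2 difference (horizontal axes) of the measured members of each of 33 gene lists (vertical axis) in the 3 comparisons; filled points mark a camera adjusted p under 0.05 with the preset correlation. CLOCK-BMAL1 activated genes lay at -0.87 in mutant against wild type, 0.11 in rescue against mutant and -0.60 in rescue against wild type.

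The median, mean and test of a list differed in sign only among lists that were not called. In mutant against wild type these were the adipocyte, bile duct, female-biased, heat shock, male-biased, NAD and red cell lists. In rescue against mutant they were the adipocyte, bile acid, heat shock, lymphocyte, NAD and PPARA lists, and in rescue against wild type the bile acid, female-biased, heat shock, inflammatory, NAD, NRF2, PPARA, stellate and sex chromosome lists. No list was called with an estimated correlation in any comparison; fry, which tests whether genes of a list move one way on balance, called 5, 1 and 2 lists in the 3 comparisons.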

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

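These probe sets were counted after the main comparisons had been seen. Probe sets with no annotation were outside every comparison of named genes, and some carried a signal that differed between groups. Among 5529 such probe sets, 429 were called between mutant and wild type (248 higher, 181 lower), 118 between rescue and mutant (92 higher, 26 lower) and 76 between rescue and wild type (54 higher, 22 lower), with limma adjusted over all 28939 probe sets from the first annotated number on.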

How the results depend on the processing

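Removal of the span and level trend was chosen after the data were seen; the other settings were not. Signs were checked only for the 63, 43 and 49 calls among the genes followed through the settings and for the 25 list calls. Followed genes among the dimmest 40% had no value in the setting that leaves those genes out. None of these calls changed sign under any setting in which it was tested. The enrichment near Clock did, and so did small differences of genes without a call, such as Dbp, Per3, Per1, Usp2 and Nampt in rescue against mutant. A 2-fold minimum left 147, 42 and 56 genes in mutant against wild type, rescue against mutant and rescue against wild type. An adjusted p under 0.1 gave 1601 and 816 genes in both rescue comparisons and 3895 in the F test. Without the dimmest 40% of genes, which leaves fewer genes to adjust over, the rescue comparisons gave 1178 and 711 genes, 924 turned-back genes and 6 shifted lists in rescue against mutant. A trended and robust prior gave 1210 and 704 genes and 904 turned back, and array weights 1334 genes in rescue against mutant and 938 turned back; the cause was not tested.

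Leaving out 1 array at a time gave 1695 to 3130 genes for mutant against wild type (lowest without wild-type replicate 3, and 2035 without Clock mutant replicate 1), 200 to 692 for rescue against mutant and 233 to 501 for rescue against wild type. The F test gave 1561 (without wild-type replicate 3; 1611 without Clock mutant replicate 1) to 2443 genes. The number turned back ran from 151 to 439, with 151 and 155 without rescue replicates 3 and 2, and 154, 248 and 260 without Clock mutant replicates 1, 2 and 3. Recovery ran from 29.3% to 42.2%. Shifted lists numbered 5 to 10 (10 without wild-type replicate 3), 8 to 13 and 8 to 14 (14 without rescue replicate 2) in the 3 comparisons. The balance of rescue against wild type turned from 185 higher and 269 lower to 138 and 116 without rescue replicate 2 and 122 and 120 without wild-type replicate 1. Of 25 list calls, 18 held without any single array, 18 without the dimmest 40% of genes and 23 with the trend removed. Fewer arrays also mean less power.

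With an estimated correlation camera called 0, 0 and 0 lists, against 5, 1 and 2 with fry; with the trend removed 10 lists were called in mutant against wild type, and 0, 0 and 0 with an estimated correlation as well. Recovery was 68.8% with the genes repressed by REV-ERB alone. Near Clock, the odds ratio of 1.42 fell to 1.19 (p = 0.322, Fisher's exact test) with quantile normalization repeated and 1.13 with the trend removed. It ran from 0.923 to 1.43 with 1 array left out, and was reversed at 0.954 (p = 0.91) without wild-type replicate 1 and 0.923 (p = 0.815, Fisher's exact test) without Clock mutant replicate 1. It was 1.25 and 1.2 without wild-type replicates 2 and 3, 1.08 and 1.09 without Clock mutant replicates 2 and 3, and 1.34 and 1.36 without rescue replicates 1 and 3. With windows of 50 and 200 genes it was 2.04 and 1.32.

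What the replicate numbers mark is not known, and the correlations of deviations do not settle whether they pair the animals. Of 9 same-number pairs, 4 correlated above 0.1. The range was -0.11 to 0.19, against -0.26 to 0.18 for other pairs. For 4 arrays the own number correlated best in both other groups. With the replicate number as a block, 3368, 931 and 507 genes were called and 704 turned back; the F test called 2776 genes, 6, 10 and 9 lists shifted and the odds ratio near Clock was 1.43. Clock itself was then called in rescue against mutant (-0.66, adjusted p = 0.0158), as it was with array weights (-0.82, adjusted p = 0.0454). Of 63, 43 and 49 calls among the genes followed through every setting, 60, 28 and 39 held without any single array, and 60, 37 and 45 under every other planned setting; no such call reversed. Clock and Nr1d1 in mutant against wild type, and Mrc1, Thrsp, Per1, Arntl and Ifih1 in rescue comparisons, were among those lost. Precision is lowest for dim genes, where RMA compresses differences.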

Other observations

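Some gene families were looked at after the data were seen, without a test of the families. Of 85 respiratory chain and ATP synthase genes, 26 rose and 1 fell between mutant and wild type (median 0.30, limma adjusted p under 0.05 for each call), and 7 fell and none rose between rescue and mutant (median -0.25). Of 67 ribosomal protein genes 17 rose and 1 fell in mutant (median 0.25), and 6 fell and 1 rose in rescue against mutant (median -0.25). With the trend on gene span and level removed, the medians in mutant against wild type were 0.20 and 0.14. Both directions also held with quantile normalization repeated and with median centring, but the counts moved. Respiratory chain genes lower in rescue against mutant numbered 18 and 5 in these settings, with none higher. Ribosomal protein genes higher in mutant than in wild type numbered 22 and 10, with 2 lower in each. The median of all genes was 0.07 in the same direction, and the other families counted moved that way too: 31 of 1027 olfactory receptor genes rose and 4 fell (median 0.10), 2 of 167 vomeronasal receptor genes rose (0.08), 21 of 291 microRNAs rose and 1 fell (0.14), and 9 of 51 small nucleolar RNAs rose and 5 fell (0.15). With the trend removed the medians of these 4 families were 0.00404, 0.00402, -0.00424 and -0.0069, the last pair with the sign turned. Olfactory receptor genes then numbered 9 higher and 14 lower, vomeronasal 1 and 0, microRNAs 8 and 6 and small nucleolar RNAs 5 and 7. With median centring 10 olfactory receptor genes were higher and 7 lower.

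Genes called in 1 direction against both other groups were also counted after the data were seen, and the examples were chosen from their values. A set of 41 genes stood apart in rescue from both other groups, 26 higher and 15 lower. The higher genes included Gpr65, Pfkfb3, Ptprc, Chrna4, Abcb1a, the vasopressin receptor gene Avpr1a, the cadherin gene Cdh1 and the tight junction gene Cldn1, and the lower ones Cyp7a1 and Atp6v0d2. Cldn1 was 0.56 above mutant and 1.16 above wild type, and Cdh1 was 1.01 and 0.65 above.

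For the 3 patterns that follow, all tests were chosen after the result was seen, except the counts of other splits and camera with an estimated correlation on the values as deposited. The first pattern is that long genes were lower and short genes higher in mutant livers. With the trend on span and level removed, 2043 of the 3068 calls remained, so the trend alone does not account for most calls. An additive background offset in the mutant arrays would raise dim short genes most. Among the shortest genes the brightest 308 rose more than the dimmest 1577, by 0.169 (bootstrap interval over genes 0.111 to 0.221). RMA subtracts background and compresses differences of dim genes, so this cannot decide whether there was an offset. RNA integrity or amplification that differed between groups may still have produced the trend: every mutant array had a lower trend than the other 6 arrays, with a gap of 0.13 in rho, but extraction and genotype cannot be told apart. An effect of the genotype on long genes was not tested and stays open.

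The second pattern is the lower level of endothelial and Kupffer cell markers in mutant livers. The span trend does not account for it, since with the trend removed both lists kept a camera adjusted p of at most 2.51e-08 (medians -0.403 and -0.515), although with an estimated correlation neither was called, with the trend removed (adjusted p = 0.309 and 0.204) or without that step (0.347 for both). A smaller share of every non-hepatocyte cell type would lower all such markers alike, yet among markers outside the dimmest 40% of genes the medians of 34 endothelial and Kupffer markers and 27 other markers differed by -0.358 (bootstrap interval -0.785 to -0.212), and by -0.349 (-0.726 to -0.155) against the 18 stellate markers, of which 5 fell. Against 4 lymphocyte markers, none of which fell, it was -0.495 (-0.878 to -0.189). Against 5 bile duct markers the interval included 0 (-1.02 to 1.31), and no neutrophil marker was bright enough. In these animals the median changes of stellate markers and of the 4 lymphocyte markers thus lay above that of endothelial and Kupffer markers. The intervals resampled markers as if independent and hold no spread between animals, so an equal loss is not ruled out. Fewer Kupffer and endothelial cells alone could account for the pattern, but 14 of the 40 markers lay over 3 SE from the mean change of their list. Probe sets with unequal background could also do that. Fewer such cells and a change of expression within them therefore cannot be told apart, and an effect of the genotype on these cells was not tested.

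The third pattern is the uneven return of clock genes in rescue. If a fixed share of cells had recovered fully, 1 share would place every gene. The best share was 12.7%, and 7 of 18 genes lay over 3 SE from it, 3 above and 4 below in level. None (0) of 1000 simulations was as heterogeneous. Of those below, Elovl3 (-10.6 SE) and Nfil3 (-4.31 SE) had risen in mutant, so a lower level is a larger return. Per3 (-3.41 SE) and Usp2 (-3.04 SE) had fallen in mutant and returned less than that share. The 1000 simulations drew error independently for each gene and used 1 share for all rescue animals, though single animals recovered 31.3, 27.2 and 53.0%. They also left out the compression of dim genes by RMA, and the 18 genes were chosen by their mutant call. The count of 0 may therefore overstate the heterogeneity. Chance error in the mutant arrays, which both comparisons share, could not be the whole cause of the return as such. With different mutant arrays in the 2 comparisons the covariance over 24 clock genes was -0.391 at the highest. Regrouped residuals gave -0.0672 at the lowest. Over all genes these values were -0.0368 and -0.0181. An even return would also give a negative covariance, so these values cannot tell whether chance error made the return uneven. An error common to all 3 mutant arrays was not tested. The injection or the plasmid apart from CLOCK may contribute, as the 41 genes that differ from both groups would be consistent with, but no control injection is described and the effects cannot be told apart. A different phase of the clock in rescue livers was not tested, since there was a single hour.

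For the 3 comparisons of 6 arrays there are 10 splits, too few for a share under 0.05. The real split called 3068, 759 and 454 genes and the highest of the others 1, 2 and 0, so 1 of 10 splits gave as many in each comparison. Shifted lists numbered 6, 10 and 9, and the highest of the other splits gave 10, 17 and 12; 7, 4 and 3 of the 10 splits gave as many. The odds ratio near Clock was 1.42 and the highest other was 0, with 1 of 10 splits as large, where the other splits called almost no gene. Of 280 partitions of the 9 arrays, 100 were used: 1 of 100 gave as many genes in the F test (2569, highest other 998) and 1 of 100 as many turned-back genes (564, highest other 428), the real grouping included in both counts.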
